A study of Mus musculus with 2 samples.

How the data were processed

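Single-cell RNA was measured in 2 libraries of immune cells, 1 with the genotype label wild type (Tdg_WT) and 1 with the label Tdg knockout (Tdg_KO). Per the labels' protocols, tumours of mice were collected at day 14 of growth, counted from inoculation, and broken up with a tissue dissociation kit, immune cells were enriched by density centrifugation over Percoll, live CD45-positive cells were sorted by flow cytometry, and droplet libraries of RNA 3′ ends were made with a 10x Genomics kit. The deposited values are raw UMI counts per gene and cell barcode, which are not normalised. Per the file headers these counts come from Cell Ranger 6.0.1. The submitters' processing notes name Cell Ranger, Seurat and the genome build mm10, with no role for each. The aligner settings and the gene annotation are not given in the sources used here. The barcodes were already reduced to called cells, with a minimum of 500 UMIs in Tdg_WT and 502 in Tdg_KO, so RNA in empty droplets could not be measured. Each library listed the same 32285 genes. The 78 entries that share a symbol with another were summed by symbol, which left 32245 symbols.

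The libraries held 39819010 UMIs in 5604 barcodes (Tdg_WT) and 52586319 UMIs in 5896 barcodes (Tdg_KO). Cells with at least 200 detected genes and at most 10% mitochondrial UMIs were kept, 5504 (98.2%) in Tdg_WT and 5693 (96.6%) in Tdg_KO. Barcodes over the mitochondrial limit were 81 and 191, and barcodes under the gene limit 30 and 38. Doublets were called per library with Scrublet at an expected rate of 0.05. It set thresholds of 0.554 and 0.406 and called 0 barcodes in both libraries, so the calling did not work here and no doublet was removed by it. Barcodes with at least 3 marker genes of each of 2 lineages were counted instead.

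Cells of both libraries were clustered together in scanpy 1.11.5 (Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9). Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with the library as batch, and 30 principal components, 15 nearest neighbours and Leiden resolution 1 were used. Mitochondrial, ribosomal protein, haemoglobin, sex-linked, immunoglobulin and T cell receptor variable genes were kept out of the variable genes. Lymphoid clusters together and mononuclear phagocyte clusters together were clustered again in the same way. Clusters were named from 24 marker sets by the mean standardised expression of the markers, where at least 3 markers were each detected in 10% of the cells. A cluster stayed unnamed where its 10 leading genes held more markers of another type, where 3 or more of them were proliferation or type I interferon genes, or where its cells had under 1/3 of the median UMIs of their library and no own marker led.

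After the data were seen, clusters of the second clustering were also kept unnamed where at least 50% of barcodes held genes of T cells and phagocytes (or of T cells and B cells) or, among lymphoid clusters only, at least 25% held genes of 2 lymphocyte subsets. This touched 5 clusters. The plasmacytoid dendritic-like cluster, to which the last limit did not apply, had Cd8 and Cd4 or Foxp3 UMIs in 61.5% of barcodes. Of 37 clusters, 26 received a name, in 17 classes. The names rest on these markers and are written as cell-like for that reason.

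There is 1 library per group, so no test and no p-value across libraries was possible. Shares of cells are given with exact Clopper-Pearson 95% intervals. Expression was summed per class and library and divided by the class total (CPM). The ratio of CPM, Tdg_KO over Tdg_WT, has an exact conditional Poisson 95% interval. All intervals cover counting error only. The 9 classes with at least 100 cells in each library were compared. Of the 22 gene lists fixed, that of sex-linked transcripts was given no median. For the others the median log2 ratio of members with at least 50 UMIs over both libraries was taken, where at least 5 were measured. It was set against 10000 random lists of the same size matched on expression in 20 bins. The percentile is a description of these 2 libraries. In the lists 4 gene names were not found among the listed genes.

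The markers, lists, filters, classes compared and the rule for named genes were fixed before the data were examined. The rule took, per class, genes with at least 50 UMIs in the library where they were higher and detected in at least 5% of that library's cells of the class. It ranked them by the interval bound nearest to 1 and named 10 each way in the 3 largest classes and 5 each way in the others, 120 genes in all. Mitochondrial, ribosomal protein, haemoglobin, sex-linked, immunoglobulin and T cell receptor genes and gene models without a symbol of their own were left out. Tdg and, from each list described, the 2 to 4 members with the most UMIs and the 2 with the most extreme ratio were added. Other genes named, such as members followed across classes or inside single clusters, were chosen after their values were seen. Gene identifiers were those of the deposited gene list, and all 93 genes looked up were found by identifier in GENCODE vM21, whose coordinates are on mm10. Figures were drawn with matplotlib 3.10.9.

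The ratio and list functions were tested on simulated counts drawn from the Tdg_WT means at lower depth, with 200 genes changed by known folds. The simulated counts were Poisson draws, the model behind the interval, without spread between cells. Coverage near 95% was thus built in. It checks the functions and not the intervals of real counts, where 1 barcode can hold much of a gene's UMIs. At the larger of 2 simulated depths 6622 genes had enough UMIs, and the interval held the true ratio for 95.1% of the 6422 unchanged genes. The interval lay on the true side of 1 for 94.0% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold. At the smaller depth, with 2692 genes, these were 71.6%, 98.5% and 100%. For genes changed 4-fold at the larger depth the interval held the true ratio in 89.4% of 66 genes. When all members of the hypoxia and glycolysis list were lowered 1.5-fold, the estimated fold was 1.46 at the larger depth.

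Alternatives fixed beforehand were no filter on cells, a stricter filter (at least 500 genes and at most 5% mitochondrial UMIs), called doublets kept, Leiden resolutions of 0.5 and 2, genes centred within each library before clustering, and cells assigned singly by marker scores. Further ones were the compartment as denominator, scaling by the median of ratios, totals without mitochondrial and ribosomal protein genes, every cell weighted equally, cells thinned to 1000 UMIs, a minimum of 20 or 200 UMIs per list member, and a fold of 1.25 or 2. Thinning left out 189 neutrophil-like cells in Tdg_WT and 73 in Tdg_KO, and 14 macrophage-like cells in each library. Alternatives chosen after seeing the data left out the 5% of barcodes with the highest doublet scores, mixed barcodes, barcodes of another lineage within a class, and barcodes low in Malat1 (under 0.2% of UMIs) or, for macrophage-like cells, high in it. They also named mixed clusters by their markers and took each of the 2 macrophage-like clusters alone. Another lineage meant at least 3 marker genes of T, NK or B cells for neutrophil-like and macrophage-like cells. For B-like cells it meant those of T cells, NK cells, phagocytes or neutrophils. In the other classes it meant those of phagocytes, neutrophils or B cells.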

Results

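The data were 2 single-cell RNA libraries of immune cells from mouse tumours, 1 for each group. The series design calls the tumours subcutaneous KP tumours, and they were taken on day 14 after inoculation, dissociated, enriched over Percoll and sorted for live cells bearing CD45, the surface protein of white blood cells. One library carries the genotype label wild type and is called Tdg_WT here, and the other carries the label Tdg knockout and is called Tdg_KO. Tdg encodes thymine DNA glycosylase, a base excision repair enzyme that removes thymine paired with guanine and takes part in DNA demethylation, and the series title places it in cancer that lacks p53. The labels do not say which cells carry the genotype, the tumour cells, the host or both. The Tdg_WT library held 5604 barcodes and 39819010 UMIs (unique molecular identifiers, each counting 1 captured RNA molecule), and the Tdg_KO library held 5896 barcodes and 52586319 UMIs. After filtering, 5504 and 5693 cells remained, with a median of 5378 UMIs and 1724 genes per cell in Tdg_WT and of 6419 UMIs and 2012 genes in Tdg_KO. The median share of mitochondrial UMIs was 1.82% in Tdg_WT and 2.47% in Tdg_KO.

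With 1 library per group, no difference below has a replicate check, and no test between the groups was possible. Every ratio is Tdg_KO over Tdg_WT. It is followed by its 95% interval, which covers counting error only and not the spread between tumours. Expression is given in CPM, the UMIs of a gene scaled to the total UMIs of its cell class in that library.

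The gene named in the genotype label was measured first. Tdg (ENSMUSG00000034674, a protein-coding gene on chromosome 10 at 82629828 to 82650799, plus strand, mm10) had 993 UMIs or 25.1 CPM over all kept cells of the library labelled Tdg_WT. In the library labelled Tdg_KO it had 1385 UMIs or 26.5 CPM, a ratio of 1.06 (0.974 to 1.15). Its level was thus not lower in the immune cells of the library labelled as knockout. Among CD8 T-like cells the ratio was 1.40 (1.03 to 1.92), and among neutrophil-like cells it was 0.651 (0.320 to 1.24), from 40 and 13 UMIs. UMIs of this assay come from the 3′ end of a transcript, so a deletion elsewhere in the gene could leave the count as it was, and the level does not check the label. The directions below are therefore those of the library labelled Tdg_KO against the library labelled Tdg_WT.

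The first comparison asked which immune cell types made up each library. Neutrophil-like cells, short-lived phagocytes that enter tumours from the blood, were 12.5% of cells in Tdg_WT and 4.23% in the library labelled Tdg_KO, a ratio of 0.339 (0.291 to 0.393). B-like cells were 5.41% and 3.39% (0.626, 0.520 to 0.753), and naive-like T cells, marked by Lef1 and Dapl1, were 5.18% and 3.0% (0.580, 0.477 to 0.704). CD8 T-like cells, the cytotoxic T cells, were 6.29% and 7.59% (1.21, 1.05 to 1.39), NK-like cells were 15.2% and 17.1% (1.13, 1.03 to 1.24), and γδ T-like cells, led by Il17a and Cd163l1, were 2.09% and 3.07% (1.47, 1.16 to 1.88). Treg-like cells, the Foxp3-bearing T cells that restrain immune responses, were 8.28% and 8.19% (0.988, 0.866 to 1.13).

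CD4 T-like cells other than Treg-like cells were 13.4% in Tdg_WT and 11.7% in Tdg_KO (0.870, 0.782 to 0.967). Macrophage-like cells were 4.60% and 5.27%, with an interval that holds 1 (1.15, 0.967 to 1.36). Monocyte-like cells were 2.29% and 1.30% (0.568, 0.420 to 0.763). The neutrophil-like cells fell into a pair of clusters, and both were smaller in Tdg_KO. The cluster led by G0s2, Il1f9 and Slpi was 7.10% and 2.74% of cells (0.386, 0.318 to 0.466). The cluster led by S100a9, S100a8 and Retnlg, with a median of 900 UMIs per cell, was 5.40% and 1.49% (0.277, 0.215 to 0.353). Of the named myeloid cells, neutrophil-like cells made up 49.1% in Tdg_WT and 25.3% in Tdg_KO, and macrophage-like cells 18.1% and 31.5%.

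**Figure D1:**
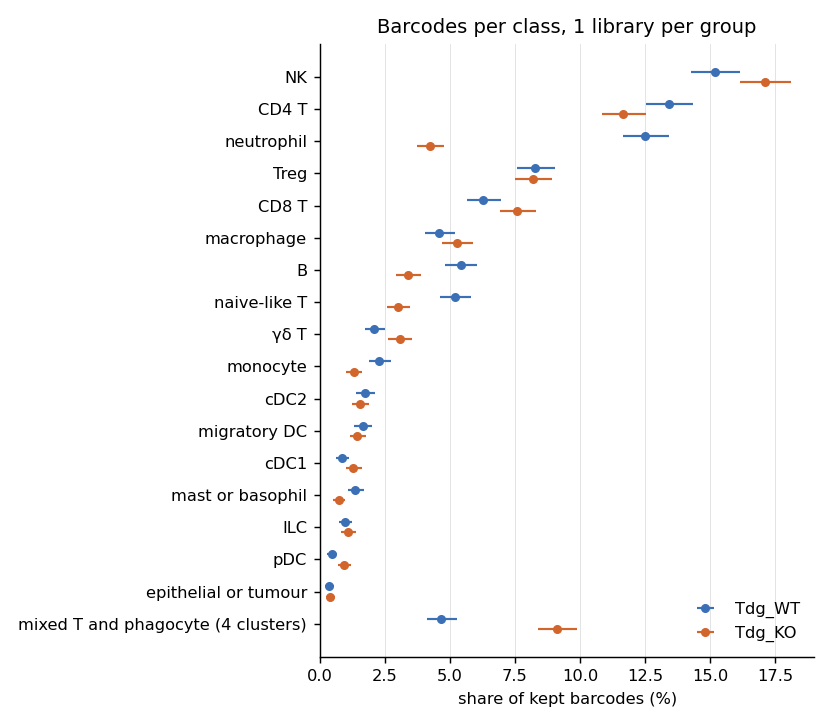
Share of kept barcodes (percent, x axis) in each cell class and in the mixed T cell and phagocyte clusters (y axis) of the Tdg_WT and the Tdg_KO library, 1 library each, with exact 95% binomial intervals that cover counting error only. Neutrophil-like cells are at 12.5% in Tdg_WT and 4.23% in Tdg_KO.

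These shares are of cells that passed the Percoll step and the live CD45 sort, so they are not shares of the tumour. Doublet calling marked 0 barcodes in either library and so removed none. Barcodes with marker genes of both T cells and phagocytes were 7.34% of the Tdg_WT library and 14.5% of the Tdg_KO library. Limits set after the data were seen kept 5 clusters of mixed barcodes out of the classes, 7.10% of the cells in Tdg_WT and 14.2% in Tdg_KO. All unnamed clusters together were 17.4% and 27.8%. When the mixed clusters were named by their markers, the monocyte-like ratio was 1.04, the macrophage-like ratio 1.49 and the Treg-like ratio 1.24. With the named myeloid cells as the denominator, the neutrophil-like ratio was 0.515 and the macrophage-like ratio 1.74. The CD8 T-like ratio was 1.06 without the barcodes with the highest doublet scores and 1.60 at Leiden resolution 0.5.

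The second comparison was of expression within the 9 classes that had at least 100 cells in each library. The hypoxia and glycolysis list holds genes that respond to low oxygen or encode sugar-breaking enzymes. Its median log2 ratio was below 0 in all 9 classes, with few members past 1.5-fold in most lymphocyte classes. The difference was widest in neutrophil-like cells, where the median log2 ratio of 21 measured members was −0.94 and 17 were at least 1.5-fold lower and 0 as much higher. In macrophage-like cells the median of 19 members was −0.89, with 17 at least 1.5-fold lower and 0 higher. The lymphocyte classes differed less, from −0.44 in CD8 T-like cells (5 lower and 1 higher of 21) and −0.34 in CD4 T-like cells (3 lower and 1 higher of 21) to −0.18 in naive-like T cells (1 lower of 13).

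The list medians were −0.33 in Treg-like (1 lower of 20), −0.26 in NK-like (1 lower of 21), −0.22 in γδ T-like (1 lower of 15) and −0.20 in B-like cells (2 lower and 2 higher of 20). In 6 classes, neutrophil-like, macrophage-like, CD8 T-like, CD4 T-like, Treg-like and NK-like, the median was below that of all 10000 random lists matched on expression. It was at percentile 0.0400 in B-like, 0.130 in γδ T-like and 1.07 in naive-like T cells. These percentiles describe the 2 libraries. Clusters of a class differed: the NK-like cluster led by Klra4, Klra8 and Eomes was at −0.06 and the others at −0.32 and −0.25, and the CD4 T-like clusters were at −0.09 and −0.42.

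The glycolytic enzyme gene Gapdh was at 2427 CPM in neutrophil-like cells of Tdg_WT and 1565 in Tdg_KO (0.645, 0.605 to 0.687), and at 5357 and 3269 CPM in macrophage-like cells (0.610, 0.585 to 0.637). Ldha, which encodes lactate dehydrogenase, had a ratio of 0.522 (0.467 to 0.583) in neutrophil-like and 0.583 (0.529 to 0.643) in macrophage-like cells, and Aldoa, which encodes aldolase, 0.627 and 0.614. Mif, a cytokine gene, was at 1518 and 661 CPM in neutrophil-like cells (0.436, 0.396 to 0.478). Bnip3 (ENSMUSG00000078566, chromosome 7 at 138890836 to 138909519, minus strand, protein coding), a mediator of the removal of mitochondria under low oxygen, was at 223 and 60.4 CPM in neutrophil-like cells (0.271, 0.197 to 0.364; 0.421 after thinning). In macrophage-like cells its ratio was 0.280 (0.214 to 0.364). Egln3, an oxygen sensor gene, was at 67.0 and 17.2 CPM there (0.257, 0.146 to 0.433). Among CD8 T-like cells, the glucose transporter gene Slc2a3 was at 62.7 and 19.8 CPM (0.316, 0.241 to 0.412) and Aldoa at 602 and 371 CPM (0.617, 0.576 to 0.661).

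The angiogenic factor gene Vegfa, a member of the list, was higher in Tdg_KO in NK-like, CD4 T-like, B-like and neutrophil-like cells. In NK-like cells it was at 374 CPM in Tdg_WT and 465 in Tdg_KO (1.24, 1.17 to 1.31), and it is a leading gene of an NK-like cluster that held 393 of 836 NK-like cells in Tdg_WT and 568 of 974 in Tdg_KO. Its ratio was 3.40 (1.82 to 6.72) in CD4 T-like, 2.59 (1.68 to 4.06) in B-like and 1.28 (1.04 to 1.56) in neutrophil-like cells. It was 2.63 in CD8 T-like cells but 0.456 after thinning, and 0.683 (0.437 to 1.06) in macrophage-like cells.

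**Figure D2:**
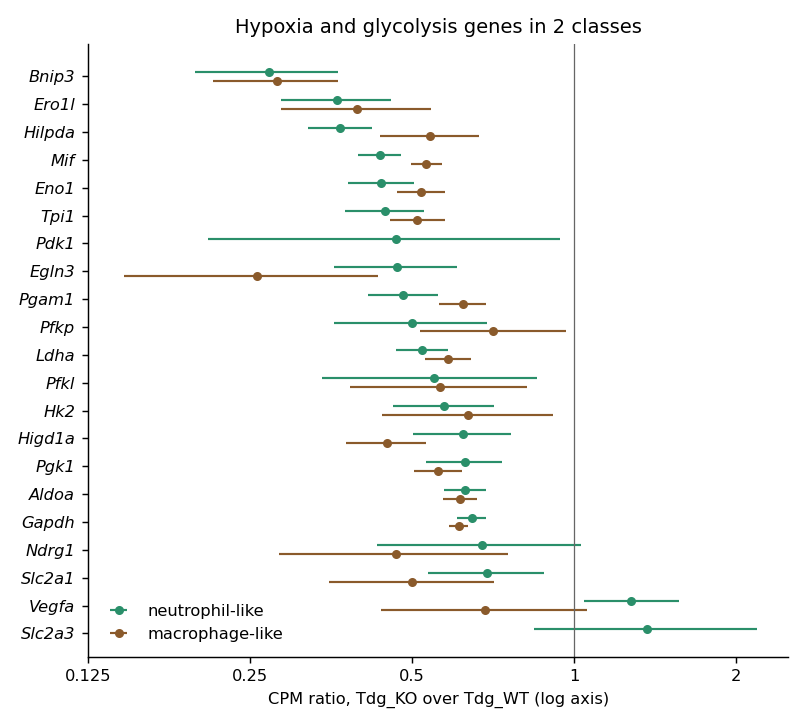
CPM ratio (log axis), Tdg_KO over Tdg_WT, of each measured member of the hypoxia and glycolysis list (y axis) in neutrophil-like and macrophage-like cells, with 95% counting intervals, 1 library per group. In each of the 2 classes 17 members lie at least 1.5-fold lower in Tdg_KO.

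The dissociation and stress response list, made of immediate early and heat shock genes that respond to handling, also differed between the libraries. Its median was above the middle 95% of random lists in 6 classes, at 0.74 in macrophage-like, 0.30 in B-like, 0.28 in γδ T-like, 0.20 in NK-like, 0.17 in Treg-like and 0.10 in CD8 T-like cells. With every cell weighted equally it fell inside that range in CD8 T-like (0.04) and γδ T-like cells (0.05). It was 0.19 in neutrophil-like, 0.03 in CD4 T-like and −0.07 in naive-like T cells, inside that range. Of the 158 list medians described over the 9 classes, 75 lay outside the middle 95% of their random lists. After thinning every cell to 1000 UMIs, the hypoxia and glycolysis median of naive-like T cells was 0.15 and that of γδ T-like cells −0.49. The median of B-like cells was −0.55 without the barcodes with the highest doublet scores, and that of NK-like cells −0.16 with every cell weighted equally. The hypoxia and glycolysis median fell inside the range of random lists in B-like cells without barcodes of another lineage (−0.09), in γδ T-like cells without barcodes low in Malat1 (−0.13) and in naive-like T cells under 4 settings.

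**Figure D3:**
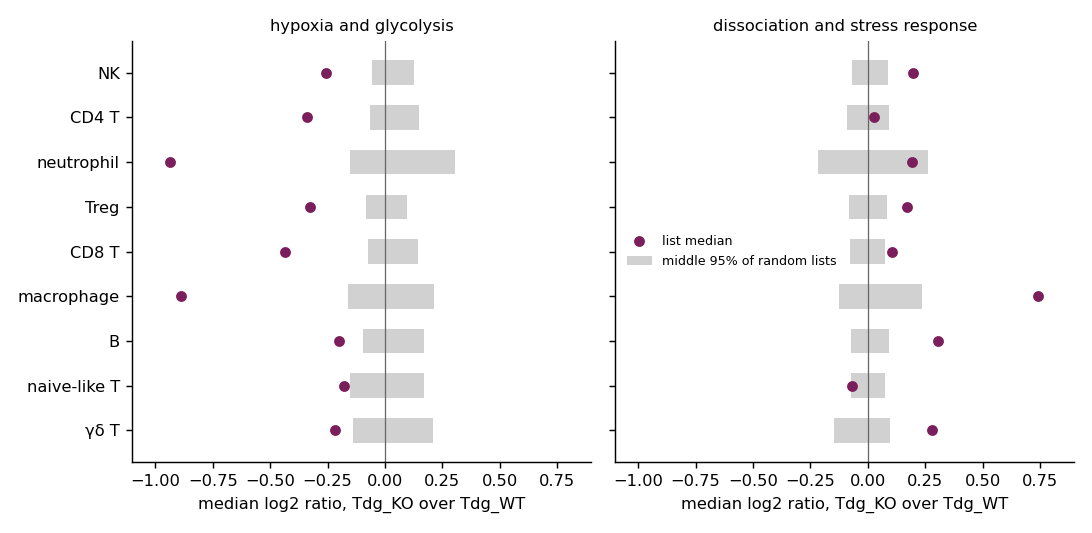
Median log2 ratio (x axis, Tdg_KO over Tdg_WT) of the hypoxia and glycolysis list (left) and the dissociation and stress response list (right) in 9 cell classes, with grey bars for the middle 95% of 10000 random lists matched on expression, 1 library per group. The hypoxia and glycolysis median lies below the grey bar in all 9 classes.

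NK-like cells, innate lymphocytes that kill target cells, were the largest class, with 836 cells in Tdg_WT and 974 in Tdg_KO. Genes of the cytotoxic effector list had a median log2 ratio of −0.11 over 20 members (percentile 0.120), with 2 at least 1.5-fold lower and 1 higher. The chemokine gene Ccl5 was at 9255 and 6904 CPM (0.746, 0.737 to 0.756), and the granzyme gene Gzma had a ratio of 0.842 (0.828 to 0.856). Both are among the leading genes of an NK-like cluster that held 191 of 836 NK-like cells in Tdg_WT and 153 of 974 in Tdg_KO. Gzma is also a leading gene of the NK-like cluster led by Klra4, Klra8 and Eomes, which moved the other way, from 393 of 836 to 568 of 974. The granzyme gene Gzmf was at 546 and 173 CPM (0.316, 0.295 to 0.339) and Gzmc at 1984 and 1128 CPM (0.568, 0.552 to 0.585). Gzmc leads an NK-like cluster that held 252 of the 836 NK-like cells in Tdg_WT and 253 of the 974 in Tdg_KO. Csf2, which encodes the growth factor GM-CSF, was at 28.1 and 7.05 CPM (0.251, 0.177 to 0.350) and had a ratio of 0.495 with the stricter cell filter. Upp1, a uridine phosphorylase gene, had a ratio of 0.380 (0.295 to 0.488), and 0.221 after thinning. The metallothionein gene Mt1 had a ratio of 0.299 (0.254 to 0.351), with 37% of its UMIs in 1 barcode, and was at 0.847 when no cell was filtered out. Upp1 and Mt1 were each lower, with the whole interval below 1, in 5 of the 8 other classes.

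Other genes were higher in NK-like cells of the library labelled Tdg_KO. Eya2, a transcriptional coactivator gene, was at 9.68 and 22 CPM (2.28, 1.65 to 3.18), the Src-family kinase gene Lyn at 58.4 and 96.4 CPM (1.65, 1.44 to 1.89), and the growth factor gene Pdgfa at 20.8 and 42.4 CPM (2.04, 1.63 to 2.56; 1.35 after thinning). Fbxo32, a ubiquitin ligase gene, had a ratio of 1.80, Spsb1 1.79 and Bahd1 2.38. The linker histone gene Hist1h1c was lower in Tdg_KO (0.598, 0.547 to 0.652). The histone gene Hist1h2bc was lower in NK-like cells (0.441, 0.384 to 0.507; 0.248 after thinning), in CD4 T-like cells (0.359, 0.298 to 0.430) and in Treg-like cells (0.246, 0.190 to 0.315; 0.432 with mixed clusters named). Neither histone difference was particular to NK-like cells. Each gene was lower, with its whole interval below 1, in 7 of the 8 other classes.

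In CD4 T-like cells of the library labelled Tdg_KO, 3 genes of interferon-induced transmembrane proteins were lower, while the medians of the type I interferon (0.24, 1 higher of 10) and interferon gamma response lists (0.10, 2 higher of 13) were above 0, inside the range of random lists. Ifitm1 (ENSMUSG00000025491, chromosome 7 at 140967221 to 140969825, plus strand, protein coding) was at 250 and 46.8 CPM (0.187, 0.159 to 0.220; 0.110 after thinning), Ifitm2 at 507 and 257 CPM (0.507, 0.469 to 0.547), and Ifitm3 had a ratio of 0.531 (0.464 to 0.608). Ifitm1 and Ifitm2 were each lower, with the whole interval below 1, in 6 of the 8 other classes, and Ifitm3 in 3 of them. The chemokine gene Ccl1 was at 1276 and 592 CPM (0.464, 0.442 to 0.488), and the interleukin 1 decoy receptor gene Il1r2 at 145 and 75.3 CPM (0.520, 0.450 to 0.599). Both are leading genes of a CD4 T-like cluster that held 367 of 738 cells in Tdg_WT and 286 of 664 in Tdg_KO. Csf2 had a ratio of 0.322 (0.280 to 0.369), with 35% of its UMIs in 1 barcode, and 0.178 without barcodes of another lineage. Gzmc had a ratio of 0.279 (0.225 to 0.343), with 25% in 1 barcode. The integrin genes Itga4 (45.6 and 92.3 CPM, 2.02, 1.69 to 2.42) and Itga1 (2.08, 1.54 to 2.84) were higher in Tdg_KO.

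The cytotoxic effector list had a median of −0.26 in CD4 T-like cells, with 2 members at least 1.5-fold lower and 1 higher of 18, and −0.39 with the stricter cell filter. Ifng, the interferon gamma gene, had a ratio of 0.706 (0.651 to 0.765) and Ccl5 one of 1.14 (1.08 to 1.21). The T cell activation and costimulation list had a median of −0.20 (2 lower and 0 higher of 15), the Treg suppressive programme list −0.30 (2 lower and 0 higher of 12), and the checkpoint and exhaustion list −0.11 (2 lower and 2 higher of 16). After thinning the last was 0.11 and the activation list −0.05, inside the range of random lists.

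CD8 T-like cells of the library labelled Tdg_KO also had less Ifitm1, at 572 CPM in Tdg_WT and 127 in Tdg_KO (0.223, 0.202 to 0.246). Ifng was at 298 and 111 CPM (0.375, 0.334 to 0.420), while the chemokine gene Xcl1 was higher in Tdg_KO (1.27, 1.22 to 1.32) and Ccl5 lower (0.878, 0.857 to 0.90). Over the cytotoxic effector list the median was −0.26, with 4 members at least 1.5-fold lower and 1 higher of 20. It was −0.12 with the stricter cell filter and −0.40 with every cell weighted equally. The checkpoint and exhaustion list had a median of −0.08 over 17 members, at the lower bound of the random lists. It was −0.19, outside their range, without the highest doublet scores, and 0.04 after thinning. In it, the transcription factor gene Tox had a ratio of 1.55 (1.29 to 1.86) and the inhibitory receptor gene Havcr2 one of 0.717 (0.543 to 0.948). The proliferation list was higher in Tdg_KO, at 0.29 with 3 members at least 1.5-fold higher and 1 lower of 12, and Pclaf, a gene of DNA replication, at 2.81. With every cell weighted equally the median was 0.22, inside the range of random lists. The Fc receptor chain gene Fcer1g was at 50.9 and 130 CPM (2.55, 2.12 to 3.07), and the carbonic anhydrase gene Car2 had a ratio of 2.05 (1.66 to 2.56). Csf2 had a ratio of 0.292 (0.212 to 0.398), with 46% of its UMIs in 1 barcode, and 0.489 with the stricter cell filter.

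Treg-like cells differed little in the genes of their own programme. The Treg suppressive programme list had a median of −0.01 over 15 members (percentile 40.5). Tnfrsf4, a costimulatory receptor gene, had a ratio of 0.926 (0.895 to 0.958), the checkpoint receptor gene Ctla4 0.939 (0.897 to 0.982), and the semaphorin receptor gene Nrp1 1.62 (1.31 to 2.02). The heat shock genes Hsph1 (41.4 and 89.9 CPM, 2.17, 1.74 to 2.73) and Hspa1a (1.79, 1.61 to 2.0) were higher in the library labelled Tdg_KO. They were also higher, with the whole interval above 1, in 6 (Hsph1) and 4 (Hspa1a) of the 8 other classes. The base excision repair and cytosine demethylation list, to which Tdg belongs, had a median of 0.29 over 8 members (percentile 99.0) and of −0.01 after thinning. S100a8 and S100a9, neutrophil genes, were far lower in Treg-like barcodes of Tdg_KO, at 0.0367 and 0.0564, and 27% and 54% of their UMIs lay in 1 barcode. With no filter on cells they were at 0.13 and 0.413.

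In naive-like T cells the nuclear receptor gene Nr4a3 was higher in the library labelled Tdg_KO, at 92.4 and 189 CPM (2.04, 1.65 to 2.53). Samsn1 was lower at 397 and 208 CPM (0.523, 0.448 to 0.610), as were the heat shock genes Hspa1a (0.668, 0.609 to 0.732) and Hspa1b (0.543, 0.479 to 0.614). In γδ T-like cells S100a6, a calcium-binding protein gene, was at 3257 and 1975 CPM (0.606, 0.572 to 0.642). Some genes of other cell types differed in γδ T-like barcodes. H2-Aa was at 7.49 (4.14 to 14.9) and Apoe at 6.88 (4.78 to 10.2), with 40% of its UMIs in 1 barcode, and they were at 3.27 and 0.999 with mixed barcodes left out. The neutrophil genes S100a8 (0.0226) and S100a9 (0.0647) were lower, with 74% and 69% of their UMIs in 1 barcode, and at 0.389 and 0.851 with no filter on cells. In B-like cells the heat shock gene Hspb1 was at 3.04 (2.36 to 3.95), with 40% of its UMIs in 1 barcode, and at 1.82 with the stricter cell filter. Genes of other lineages differed there too, with the T cell chemokine gene Ccl1 at 31.2 (16.6 to 66.1), with 47% of its UMIs in 1 barcode, and the granzyme gene Gzmb at 0.216 (0.161 to 0.285). Barcodes with marker genes of another lineage were 98 of 298 B-like barcodes in Tdg_WT and 68 of 193 in Tdg_KO, and without them the Ccl1 ratio was 2.38 and the Gzmb ratio 1.06.

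Macrophage-like cells, tissue phagocytes, had more RNA of inflammatory genes and less of genes linked to alternative activation in the library labelled Tdg_KO. The pro-inflammatory myeloid list had a median log2 ratio of 0.90 over 13 members (percentile 100), with 8 at least 1.5-fold higher and 1 lower. Il1b, the interleukin 1 beta gene, was at 1048 and 1955 CPM (1.86, 1.73 to 2.01), Ptgs2, which encodes an inducible cyclooxygenase, at 5.83 and 59.9 CPM (10.3, 4.48 to 29.0; 4.53 with mixed clusters named), and the chemokine gene Cxcl1 had a ratio of 5.14 (2.39 to 12.6). The alternatively activated and suppressive macrophage list had a median of −0.37 over 21 members (below all random lists), with 6 lower and 1 higher. Spp1 (ENSMUSG00000029304, chromosome 5 at 104435118 to 104441050, plus strand, protein coding), the osteopontin gene, was at 3333 and 1040 CPM (0.312, 0.292 to 0.334; 0.153 with the stricter cell filter). Arg1, the arginase gene, was at 1957 and 794 CPM (0.405, 0.374 to 0.439).

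The matrix metalloprotease gene Mmp12 (0.621, 0.587 to 0.656) and the galectin gene Lgals3 (0.634, 0.606 to 0.663) were also lower in macrophage-like cells of Tdg_KO. The chemokine gene Pf4 had a ratio of 0.362 (0.330 to 0.396), and Ccl4 was at 120 and 521 CPM (4.36, 3.58 to 5.34) with 25% of its UMIs in 1 barcode. Its ratio was 1.93 in the cluster led by Spp1, Arg1 and Mt2. MHC class II presentation genes were higher (median 0.57, 5 of 11 at least 1.5-fold higher, percentile 99.97), with Cd74 at 1.62 (1.59 to 1.65) and H2-Ab1 at 1.56 (1.52 to 1.61). Complement and phagocytosis genes had a median of 0.61 (7 of 13 higher), with C1qa at 1.57 (1.5 to 1.65) and the complement factor gene Cfb at 2.68 (2.09 to 3.45). In the stress list 11 of 20 members were at least 1.5-fold higher, among them Hspa1a at 5.57 (4.06 to 7.78; 1.52 with mixed clusters named), with 32% of its UMIs in 1 barcode, and Junb at 1.94 (1.70 to 2.22). The cytotoxic effector list had a median of 1.27 over its 5 measured members (4 higher), among them Ccl3, Ccl4 and Ccl5, and of 0.28, inside the range of random lists, with every cell weighted equally. Ccl3 and Ccl4 are also members of the pro-inflammatory list, so these 2 list results overlap. Among genes of other cell types, the neutrophil genes S100a8 and S100a9 had ratios of 0.222 and 0.270, and of 0.526 and 0.579 with the stricter cell filter.

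The macrophage-like cells were split differently over their clusters in the 2 libraries. The cluster led by Ccl8, C1qb and C1qc held 128 cells in Tdg_WT and 234 in Tdg_KO, and the cluster led by Spp1, Arg1 and Mt2 held 125 and 66, so these genes define the clusters as well. Within the first cluster Spp1 had a ratio of 0.403 and Arg1 of 0.494, and within the other cluster of 0.609 and 0.734. C1qa had a ratio of 1.26 within the first and of 0.916 (0.797 to 1.05) within the other. The list medians within the first and the other cluster were 0.95 and 0.77 for the pro-inflammatory list, −0.72 and −0.57 for hypoxia and glycolysis, and −0.31 and −0.23 for alternative activation. They were 0.21 and 0.16 for MHC class II presentation and 0.25 and 0.08 for complement and phagocytosis. With the mixed clusters named by their markers, the MHC class II median was 0.08, the complement median −0.11, the pro-inflammatory median 0.49 and the alternative activation median −0.76. The stress median was 0.56 within the first cluster, 1.56 within the other and 0.36 with every cell weighted equally. With 1 library per group, handling cannot be told apart from the genotype as a source of the inflammatory gene differences.

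Most macrophage-like barcodes held little of the nuclear RNA Malat1 (ENSMUSG00000092341, a lincRNA gene on chromosome 19 at 5795690 to 5802672, minus strand). Malat1 was under 0.2% of UMIs in 223 macrophage-like barcodes of Tdg_WT (88.1%) and in 268 of Tdg_KO (89.3%). Among neutrophil-like barcodes these were 270 (39.2%) and 77 (32.0%). The 2 neutrophil-like clusters were unlike. In that led by S100a9, S100a8 and Retnlg the shares were 89.2% in Tdg_WT and 87.1% in Tdg_KO. In that led by G0s2, Il1f9 and Slpi they were 1.28% and 1.92%.

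**Figure D4:**
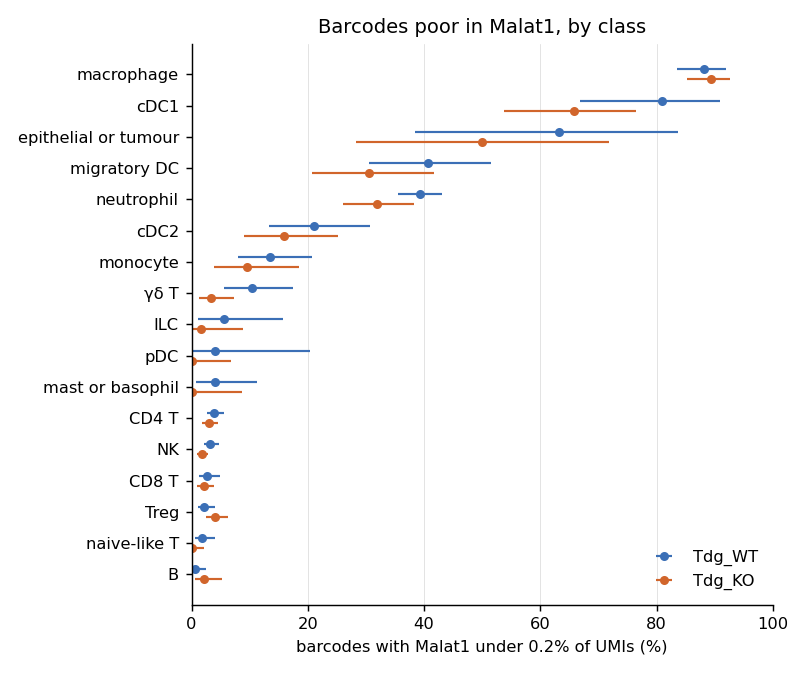
Share of barcodes (percent) with Malat1 under 0.2% of UMIs by cell class in the Tdg_WT and the Tdg_KO library, 1 library each, with exact 95% binomial intervals. Macrophage-like barcodes stand at 88.1% and 89.3%.

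Among the genes lower in neutrophil-like cells of the library labelled Tdg_KO, 2 outside the hypoxia and glycolysis list were Inhba and Wfdc21. Inhba, which encodes a subunit of activin, was at 185 and 31.4 CPM (0.170, 0.109 to 0.254; 0.294 with every cell weighted equally), and Wfdc21 at 363 and 109 CPM (0.300, 0.238 to 0.375). Of that list, the lipid droplet gene Hilpda was at 834 and 307 CPM (0.368, 0.321 to 0.421), and Ero1l, an oxidase gene of the endoplasmic reticulum, had a ratio of 0.362 (0.285 to 0.456). The neutrophil suppressor-like programme list had a median of −0.32 over 18 members (percentile 0.410), with 4 at least 1.5-fold lower and 0 higher. It was −0.59 with median of ratios scaling but fell inside the range of random lists under 5 settings, to −0.06 without the highest doublet scores. In it, S100a9 had a ratio of 0.769, S100a8 of 0.659 and Arg1 of 0.384. S100a9 and Wfdc21 are leading genes of a neutrophil-like cluster that held 297 of 688 cells in Tdg_WT and 85 of 241 in Tdg_KO. S100a8 is a leading gene of both neutrophil-like clusters. The chemokine ligand list had a median of −0.40 (5 lower and 2 higher of 12; −0.06, inside that range, with every cell weighted equally), with Cxcl2 at 0.736 (0.725 to 0.747) and Cxcl3 at 0.488 (0.458 to 0.520). The lipid handling and lysosome list stood at −0.35 (5 lower and 0 higher of 15; −0.06, inside the range, without barcodes of another lineage), with the lipid droplet coat gene Plin2 at 0.431 (0.370 to 0.50). The maturation and granule list had a median of −0.07 over 9 members, inside the range of random lists.

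Genes of other lineages were higher in neutrophil-like barcodes of Tdg_KO. The cytotoxic effector list had a median of 1.08 (9 higher and 1 lower of 17), the T cell activation and costimulation list 1.18 (8 of 10 higher) and the MHC class II list 1.04 (5 of 7 higher). Without barcodes of another lineage the cytotoxic median was 0.28, inside the range of random lists, and without the highest doublet scores the T cell activation median was 0.53. The MHC class II median rose under the same settings, to 2.02 and 2.21. For neutrophil-like cells the first setting took out barcodes with T cell, NK cell or B cell genes only. It could not remove MHC class II RNA admixed from macrophages or dendritic cells. T cell marker UMIs per neutrophil-like barcode were 2.23 in Tdg_WT and 6.44 in Tdg_KO, against 50.6 in T-like cells. Gzmb had a ratio of 5.51, and of 0.479 without the barcodes that held marker genes of another lineage. Over all measured genes the median log2 ratio was 0.17 in neutrophil-like and 0.09 in macrophage-like cells. Scaling by the median of ratios lowered every log2 ratio by 0.27 in neutrophil-like and by 0.10 in macrophage-like cells.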

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

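The tests on barcodes poor in nuclear RNA for the neutrophil-like share and for 7 single classes, on the mix of clusters (which replaced a test that took 4 whole classes as clusters), on handling, and both tests on mixed barcodes were chosen only after the result was seen.

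The neutrophil-like share was lower in the Tdg_KO library, at 12.5% and 4.23%. Neutrophils broken after the sort would have left their RNA free in all barcodes alike, but S100a8 and S100a9 over NK-like, CD4 T-like, CD8 T-like, Treg-like and B-like cells were at 95.8 CPM in Tdg_WT and 54.5 CPM in Tdg_KO, a ratio of 0.569 (0.526 to 0.616), and 37.3 and 9.19 CPM without the 10 barcodes that held the most. S100a9 was higher in Tdg_KO in CD4 T-like (1.27, 1.07 to 1.51) and B-like cells (2.84, 2.28 to 3.54), where 273 of 480 and 358 of 369 UMIs of both genes lay in 1 barcode, but the share of cells with any of these UMIs was lower in each of the 5 classes, 14.2% to 18.8% in Tdg_WT and 5.70% to 7.41% in Tdg_KO. Barcodes of few UMIs lost in cell calling are argued against by barcodes with at least 2000 UMIs, where the ratio of shares was 0.364 (0.293 to 0.448), and a lower number of barcodes poor in nuclear RNA by those with Malat1 at 0.2% of UMIs or more, where it was 0.366 (0.304 to 0.440). Loss before or during the Percoll step and the sort was not testable, and a difference between the tumours by genotype may be the source but stays an untested hypothesis with 1 tumour library per group.

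The median of the hypoxia and glycolysis list was below 0 in all 9 classes. Free RNA of 1 source in Tdg_WT would have added alike to all classes, but the excess UMIs per barcode were 14.3 times as many in CD8 T-like as in naive-like T cells (8.59 to 40.7). Another mix of clusters as the whole cause is argued against by medians of −0.87 to −0.16 with the mix of finer clusters held as in Tdg_WT, narrowly in naive-like T (−0.164, with random lists spread by 0.1601) and γδ T-like cells (−0.185, 0.175), while the macrophage-like median went from −0.89 to −0.50. Among barcodes with Malat1 at 0.2% or more, the highest median of neutrophil-like cells and 6 lymphocyte classes was −0.18, which argues against the share of barcodes poor in nuclear RNA there, but for γδ T-like cells (−0.13) it cannot be told apart, within the same 0.175, and macrophage-like cells had too few such barcodes (30 and 32). Handling cannot be told apart from the genotype either, because the stress list lay outside the random lists in 6 of the 9 classes (2 of these, CD8 T-like and γδ T-like, fell inside with every cell weighted equally) and each genotype has 1 library, so another oxygen supply of the tumours and another handling may both be candidate explanations.

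Barcodes with marker genes of both T cells and phagocytes, a signal outside the classes, were at 7.34% in Tdg_WT and 14.5% in Tdg_KO, a ratio of 1.98 (1.75 to 2.23). Chance pairs of 2 cells in 1 droplet would have raised T cell and B cell barcodes alike. T cell and phagocyte barcodes, set against those expected from barcodes of 1 lineage alone, rose 1.54 times (0.971 to 2.42) as much. They rose 1.73 times (1.14 to 2.62) as much with B cell and phagocyte barcodes added to the reference. With 2 genes of each lineage as the limit in place of 3, these values were 1.18 (0.795 to 1.74) and 1.40 (0.971 to 2.02). With only 66 and 51 T cell and B cell barcodes at the limit of 3, chance pairs thus cannot be told apart from T cells bound to phagocytes. By this count free phagocyte RNA cannot be told apart either, since phagocyte genes were more frequent in T cell barcodes of Tdg_KO by 1.42 times (1.002 to 2.03) as much as in B cell barcodes with 3 genes of each lineage as the limit, but by 1.15 times (0.635 to 2.06) with 4. Depth was looked at only afterwards. The mixed clusters led by Il1a, Thbs1 and Tnf and by Cd209a, Penk and Cd209d had medians of 24985.5 and 23319 UMIs. Medians over all kept cells were 5378 in Tdg_WT and 6419 in Tdg_KO. Such depths argue against free RNA as the only source in these 2 clusters. The other 2 mixed T cell and phagocyte clusters were at 10824 and 8532, and for other mixed barcodes free RNA stays open. Both tests replaced earlier versions: for chance pairs, the first took shares of all barcodes and counted against them, though the B-like share itself was lower in Tdg_KO (0.626), and the next counted for them, though its expectation held the mixed barcodes themselves, and for free RNA the limit of 3 genes alone counted against it. T cells bound to phagocytes before capture, more often in one genotype, may also be a source and were not tested.

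An unnamed lymphoid cluster led by Klra1, Klra6 and Tcrg-C2, which no comparison used, was 7.16% of cells in Tdg_WT and 9.56% in Tdg_KO. An unnamed cluster with genes of several lymphocyte subsets, led by Foxp3, Dgat2 and Il2ra, was 2.43% and 5.06%. Epithelial or tumour-like cells led by Clu, Krt8 and Krt18, which the CD45 sort should have removed, were 19 in Tdg_WT and 22 in Tdg_KO.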

How the results depend on the processing

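The settings on doublet scores, mixed barcodes, mixed clusters, barcodes of another lineage, Malat1 and single macrophage-like clusters were chosen only after the result was seen. No paired analysis was possible because each group has 1 library. The Tdg ratio was 1.06 with no filter on cells and 0.989 with median of ratios scaling, within its counting interval. Of the values of the shares that answer a comparison, 105 stayed within the counting interval, 14 moved out of it and 1 reversed. A reversal was counted only where the main interval excludes 1 or, for lists, the main median lies outside the random lists. The moved values can thus lie on the other side of 1, as for Treg-like cells (1.24, 1.13 and 1.17 against 0.988). For list medians of that kind these counts were 255, 35 and 2, set against the spread of random lists, for other lists 402, 60 and 7, and for named genes 1176, 275 and 9. The setting with called doublets kept repeats the main values, because 0 doublets were called. Its values, 54 for lists and 120 for named genes, are among the unmoved ones by construction, as are those for shares. Of the 75 list medians outside the range of random lists, only 46 were put through the settings. Of these 46, 26 fell inside the range or crossed 0 under at least 1 setting. A setting that left fewer than 5 measured members gave no list median. Of the 120 named genes, thinning to 1000 UMIs per cell moved 55 and reversed 3. Thinning also weights cells equally and leaves out cells under 1000 UMIs, so the part of depth alone was not tested. Weighting every cell equally without thinning moved 33.

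Share ratios by setting were as follows. At Leiden resolution 0.5 CD4 T-like cells were at 0.757 and CD8 T-like cells at 1.60. Without the highest doublet scores CD8 T-like cells were at 1.06, within their main counting interval. With cells assigned singly Treg-like cells were at 1.13, macrophage-like at 1.56, naive-like T at 0.796, γδ T-like at 1.92 and monocyte-like at 0.867. With libraries centred naive-like T cells were at 0.716, and with mixed barcodes left out Treg-like cells were at 1.17. With mixed clusters named Treg-like cells were at 1.24, macrophage-like at 1.49 and monocyte-like, reversed, at 1.04, by construction since these clusters joined the classes. As a share of the compartment, another denominator by construction, neutrophil-like cells were at 0.515, macrophage-like at 1.74 and monocyte-like at 0.864. Apart from mixed clusters named and the compartment, the cause was not tested.

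In macrophage-like cells, with mixed clusters named, list medians were 0.0827 for MHC class II, 0.49 for pro-inflammatory genes, −0.76 for alternative activation, −0.11 for complement (reversed) and −0.28 for chemokine ligands (reversed). With the stricter filter they were −0.62 for hypoxia and glycolysis, 0.34 for MHC class II, 1.23 for pro-inflammatory genes and 0.96 for stress. The pro-inflammatory median was 0.58 with barcodes high in Malat1 left out, 0.56 with cells weighted equally, 0.56 after thinning and 0.57 with members of at least 200 UMIs. The stress median was 0.94 with barcodes of another lineage left out, 0.36 with cells weighted equally and 0.56 after thinning. In the cluster led by Ccl8 the medians were 0.21 for MHC class II, 0.25 for complement and 0.56 for stress. In that led by Spp1 they were −0.57 for hypoxia and glycolysis, 0.16 for MHC class II, 0.0796 for complement, 1.56 for stress and 0.46 (reversed) for the neutrophil suppressor-like list. The cause was not tested.

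In the other classes the hypoxia and glycolysis median was −0.16 in NK-like cells weighted equally, −1.20 in neutrophil-like cells with median of ratios scaling, −0.23 in Treg-like cells with no filter and −0.24 with the stricter filter. It was −0.55 in B-like cells without the highest doublet scores, and after thinning −0.62 in CD8 T-like, −0.49 in γδ T-like and 0.15 (reversed) in naive-like T cells. The cytotoxic effector median was −0.39 in CD4 T-like and −0.12 in CD8 T-like cells with the stricter filter and −0.40 in CD8 T-like cells weighted equally. The checkpoint median of CD8 T-like cells was −0.19 without the highest doublet scores and 0.0364 after thinning. The Treg programme in Treg-like cells was at −0.17 with mixed clusters named, and the suppressor-like list in neutrophil-like cells at −0.59 with median of ratios scaling. At a 2-fold limit 9 hypoxia members were lower in neutrophil-like and 5 in macrophage-like cells, against 17 in each at 1.5-fold. The cause was not tested, except that median of ratios scaling shifts every log2 ratio of neutrophil-like cells by the same 0.27.

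Other results that reversed were the checkpoint list in CD4 T-like cells (0.11), base excision repair in Treg-like cells (−0.0120) and type I interferon in naive-like T cells (0.0798), all after thinning. The type I interferon median in neutrophil-like cells, −0.35 with all barcodes, was 0.0764 with barcodes of another lineage left out and 0.0126 with barcodes low in Malat1 left out. Gene ratios reversed after thinning for Vegfa (0.456) and Penk (0.633) in CD8 T-like and Sdc4 (1.51) in γδ T-like cells. With barcodes of another lineage left out they reversed for Gzmb in neutrophil-like (0.479) and B-like cells (1.06) and for Ier3 in B-like cells (1.19). Without the highest doublet scores Nrgn in B-like cells was at 0.304, with barcodes high in Malat1 left out Neat1 in macrophage-like cells at 0.762, and with mixed barcodes left out Apoe in γδ T-like cells at 0.999. The cause was not tested.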

Other observations

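The values on mixed barcodes, doublet scores, Malat1, Xist, Y-linked genes and haemoglobin in this part were chosen only after they were seen. Smaller myeloid classes also differed in share between the libraries. Plasmacytoid dendritic-like cells, which make type I interferon, were 0.454% of cells in Tdg_WT and 0.931% in Tdg_KO (2.05, 1.3 to 3.44). Of these barcodes 37.2% held genes of T cells and phagocytes, and 61.5% held Cd8 and Cd4 or Foxp3 UMIs. Whether the latter came from admixed T cells was not tested. The share ratio was 2.02 with mixed barcodes left out and 1.76 without the highest doublet scores. Conventional dendritic cells of type 1, which present antigen to CD8 T cells and are marked by Xcr1 and Clec9a, were 0.854% and 1.28% (1.5, 1.03 to 2.21), with a ratio of 1.19 with the stricter cell filter and 2.59 with barcodes low in Malat1 left out. The last value rests on few barcodes, since 38 of 47 in Tdg_WT and 48 of 73 in Tdg_KO were low in Malat1. Mast or basophil-like cells, led by Il6, Il4 and Hdc, were 1.36% and 0.720% (0.529, 0.352 to 0.783). The shares of cDC2-like (0.896), migratory dendritic-like (0.871) and innate lymphoid-like cells (1.11) had intervals that hold 1. As a share of the myeloid compartment, mast or basophil-like cells were at 0.804 (0.536 to 1.19), cDC2-like cells at 1.36 (1.01 to 1.84), migratory dendritic-like cells at 1.33 (0.971 to 1.81), type 1 conventional dendritic-like cells at 2.28 (1.56 to 3.37) and plasmacytoid dendritic-like cells at 3.12 (1.90 to 5.24).

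In naive-like T cells the type I interferon response list had a median log2 ratio of −0.49 over 9 members (percentile 0.0300), with 3 at least 1.5-fold lower and 0 higher, and Irf7 at 0.576 (0.357 to 0.905). The median was 0.08 after thinning. The chemokine ligand list had a median of −0.53 in CD8 T-like cells (3 lower and 1 higher of 7), −0.32 in Treg-like cells (2 lower and 1 higher of 6) and −0.32 in NK-like cells (1 lower of 6). Each fell inside the range of random lists under at least 1 setting, at −0.14 in CD8 T-like cells with the stricter filter, −0.02 in Treg-like cells weighted equally and −0.05 in NK-like cells with members of at least 20 UMIs.

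Xist, like Malat1 an RNA kept in the nucleus, was also low in macrophage-like cells. It was at 35.0 CPM in Tdg_WT and 90.8 CPM in Tdg_KO, against 829 and 1034 CPM in CD4 T-like cells. In type 1 conventional dendritic-like cells Xist was at 6.39 and 333 CPM. T cell marker UMIs per barcode of this class were 0.128 in Tdg_WT and 12.9 in Tdg_KO, so admixed T cell RNA cannot be told apart as its source. Over all kept cells Xist had 30727 and 49835 UMIs, and the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d had 0 UMIs in both libraries. The median share of Malat1 in these dendritic-like barcodes was 0.00723% and 0.0325% of UMIs. In B-like cells of Tdg_WT, 7052 of the 7059 UMIs of the haemoglobin gene Hbb-bs lay in 1 barcode.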
